A study of Arabidopsis thaliana with 15 samples.

How the data were processed

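RNA was sequenced from inflorescence meristems of Arabidopsis thaliana in 15 libraries. The 5 groups, taken from the labels, were the wild type Col-0, myb3r1, myb3r4, myb3r1myb3r4 (called the double mutant below) and pMYB3R4::GFP-MYB3R4mNES, a line with a GFP-tagged MYB3R4 under its own promoter (called the mNES line). There were 3 replicates in each group. The labels also number the libraries by a shift experiment, 1 to 3, which equals the replicate number and is not explained. The labels do not say what mNES stands for, which background carries the transgene or which alleles the mutants hold. Each library came from a pool of 36 meristems, and the labels do not state whether the replicates came from separate sets of plants, so the p-values measure the spread between these samples.

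The deposited values were TPM per gene, that is, transcript levels corrected for length and scaled so that each library sums to 1000000. Per the submitters' processing notes, FastQC, Salmon and the TAIR10 reference were used, without versions. How transcripts were summed to genes was not stated. TPM keeps no read totals, so the depth of each library and the counting error of each value are unknown. The table held 33326 genes, of which 4636 were listed at 0 in every library. Symbols and positions came from the TAIR10.1 annotation, which gave a symbol for 98.8% of the genes tested.

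Before the data were examined, the groups, the comparisons, the threshold, the 22 gene lists, the promoter element and the rule for named genes were fixed. The plan had assumed estimated counts and a count model. Because the values were TPM, limma 3.58.1 in R 4.3.3 was used in its place on log2(TPM + 0.5). The added 0.5 sets a floor, so fold changes of genes near 0 TPM are smaller than the ratio of their TPM. Genes with a TPM of at least 1 in at least 3 libraries were tested, which left 21737. A linear model with 5 group means was fitted to all 15 libraries, with 10 residual degrees of freedom and moderated variances that followed a trend with mean level (prior degrees of freedom 3.18). Contrasts compared each of the other 4 groups with Col-0, the double mutant with each single mutant, and the mNES line with myb3r4. The interaction contrast subtracted the effect of myb3r4 in the wild-type background from its effect in the myb3r1 background. An F test compared all 5 groups together. The p-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes tested in a contrast, with a threshold of 0.05. Fold changes are on the log2 scale, and errors are standard errors (SE) of the model.

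The lists held mitotic cyclins and B-type CDKs, mitotic regulators and spindle genes, cytokinesis and phragmoplast genes, DNA replication and S phase genes, histone H4 genes, D-type cyclins, CDK inhibitors, and MYB3R, E2F and DREAM components. They also held type-A response regulators, cytokinin signalling genes, cytokinin synthesis and degradation genes, importins and exportins, meristem regulators, and floral identity and organ genes. Lists for other tissues and states covered anther and tapetum, meiosis, photosynthesis, vascular tissue, DNA damage, wounding and jasmonate, heat shock and the circadian clock. Of 307 entries, 294 were tested. Each list was tested against the other genes with camera, using a preset correlation of 0.01 between genes, with adjustment over the lists of a contrast. The test was repeated with a correlation estimated for each list. Fry was run too, which asks whether the members of a list change at all, not whether they change more than other genes. A list of 49 pollen and pollen tube genes was written after the data were seen, with falls of some members known. It replaced a broader set of genes annotated as expressed in the pollen tube or sperm cells, and no list test is reported for it. Annotated processes with 10 to 500 genes, 263 in all, were tested with Fisher's exact test against the 8994 tested genes that had an annotated process. This test treats genes as independent, so its p-values can be too small for genes that change together or share reads. It was not repeated with other scalings. Transcripts of near-identical paralogs (the histone H4 genes, the small subunits of Rubisco, LHCB1.1 and its neighbours, CDC20.1 and CDC20.2) and of overlapping genes share reads, so values of single members are uncertain.

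The MSA element (the M-phase-specific activator, the textbook binding site of MYB3R proteins) was searched in the 500 bases upstream of each gene on both strands. Genes with and without it were compared between each called set and all other tested genes with two-sided Fisher's exact tests. Correlations of fold changes across genes between contrasts that share the Col-0 libraries were set beside 20 simulations with unchanged groups against the same controls. Genes were named by rule. These were MYB3R1 and MYB3R4, the 8 genes with the largest fold change in each direction against Col-0 among those past the threshold with a mean log2 value of at least 1 and no overlap between the group and Col-0, and up to 4 members of each list with the smallest p. For the other contrasts the 5 genes with the smallest adjusted p in each direction were added, with list members already named. Genes chosen after their values were seen are marked as such.

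The model was tested on simulated values of 21737 genes, drawn as independent normal noise with the moderated variances of the fit. Known changes of 0.5, 1 and 2 were given to 50, 100 and 50 genes per contrast, all with a mean log2 value above 1. The model recovered 68% to 90% of changes of 0.5, 94% to 97% of changes of 1 and 98% to 100% of changes of 2, with 4 to 12 false calls per contrast. The simulated values follow the model, without links between genes, so real data may fare worse. Alternatives left out each library in turn, fitted only the groups compared, added the replicate number as a block, removed the filter, changed the threshold, used robust variances and used another promoter window or a shorter element. Further alternatives, chosen after seeing the data, were pseudocounts of 0.1 and 1, a minimum TPM of 5, median-of-ratios and upper-quartile scaling of the TPM, and nuclear genes alone rescaled to the same total. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15. All libraries and all columns of the table were used.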

Results

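The data describe gene expression in inflorescence meristems of Arabidopsis thaliana with altered MYB3R transcription factors, proteins known to control genes of the G2 and M phases of the cell cycle. The 15 libraries fell into 5 groups of 3, namely Col-0 as the wild type, the mutants labelled myb3r1, myb3r4 and myb3r1myb3r4, and a line labelled pMYB3R4::GFP-MYB3R4mNES. Each library held a pool of 36 meristems from plants grown in 16 h of light and 8 h of dark at 170 µmol m-2 s-1 and 21 °C by day and 17 °C by night, with stems near 1 cm. Between 20370 and 20965 genes reached a TPM of 1 in a library, and the 10 most abundant genes made up 5.42% to 6.17% of all transcripts. The depth of each library is unknown because TPM keeps no read totals.

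The target genes themselves were measured first. MYB3R1 (AT4G32730) lies on chromosome 4 from 15790133 to 15796114 and MYB3R4 (AT5G11510) on chromosome 5 from 3679748 to 3684884 in TAIR10.1. In Col-0, MYB3R1 stood at 13.1 to 13.5 TPM and MYB3R4 at 10.4 to 12.8 TPM. In the libraries labelled myb3r1, MYB3R1 was at 17.2 to 18.1 TPM, higher than in Col-0 by 0.39 on the log2 scale (SE 0.048, limma adjusted p = 0.000421, n = 3 per group). MYB3R1 was at 14.0 to 14.8 TPM in the libraries labelled myb3r4 and at 14.0 to 15.2 TPM in those labelled myb3r1myb3r4, where its change of 0.11 did not pass the test (adjusted p = 0.0742), and at 12.4 to 13.6 TPM in the mNES line. MYB3R4 was at 12.7 to 13.4 TPM in the libraries labelled myb3r4, a change of 0.21 (SE 0.066) that did not pass the test (adjusted p = 0.068), and at 10.4 to 10.9 TPM in those labelled myb3r1. In the double mutant MYB3R4 had a mean of 17.1 TPM and rose by 0.59 (adjusted p = 1.77e-05). In the mNES line MYB3R4 was at 58.9 to 63.5 TPM and rose by 2.39 (adjusted p = 3.07e-10), where reads of the transgene count toward the gene. Neither target transcript was lower in the lines named after it, and a value summed over a whole gene does not test an insertion in it. The related gene MYB3R3 (AT3G09370) rose by 0.29 in the double mutant (SE 0.083, adjusted p = 0.0122).

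**Figure D1:**
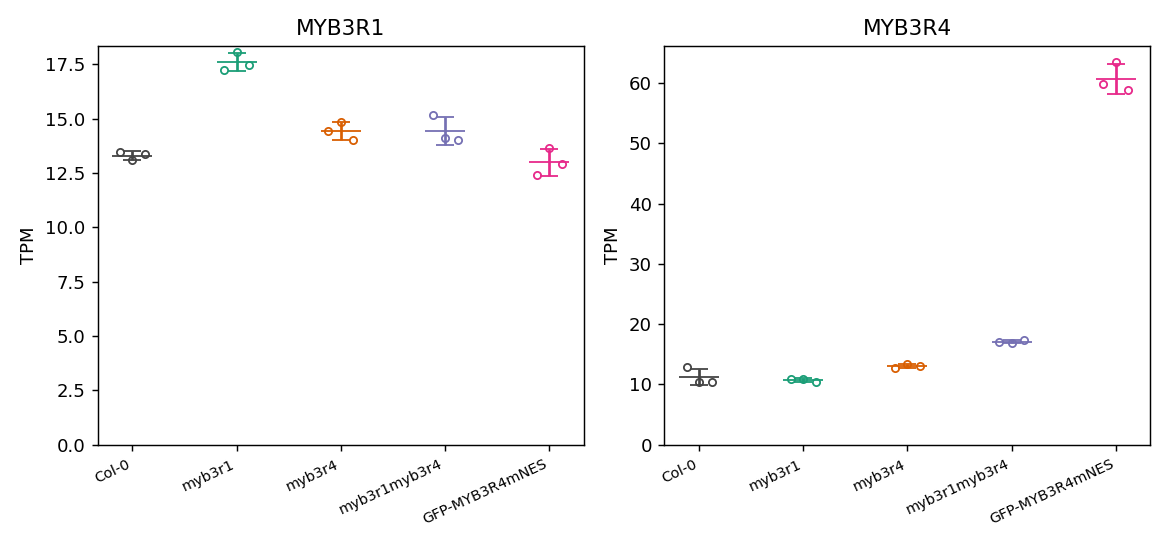
TPM of MYB3R1 (left) and MYB3R4 (right) per library, grouped by the label of the line; points are the 3 libraries of a group, horizontal lines their mean and bars 1 SD. MYB3R1 is highest in the libraries labelled myb3r1, 17.2 to 18.1 TPM, and MYB3R4 in the mNES line, 58.9 to 63.5 TPM.

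Replicates of a group resembled each other more than libraries of different groups. Across genes, log2 values correlated with r of 0.985 to 0.988 over 15 pairs of replicates and of 0.906 to 0.984 over 90 pairs from different groups; genes are not independent replicates. The median SD of a gene between replicates was 0.0761 to 0.0917 on the log2 scale. The first principal component held 51.1% of the variance, with the mNES line at -60.8 to -51.9, Col-0 at -28.2 to -16.8, myb3r4 at -3.06 to 11.6, myb3r1, which overlapped with myb3r4, from 7.94 upward with a middle value of 12.6, and the double mutant at 51.2 to 66.0. In the F test across groups, 12160 of 21737 genes differed.

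**Figure D2:**
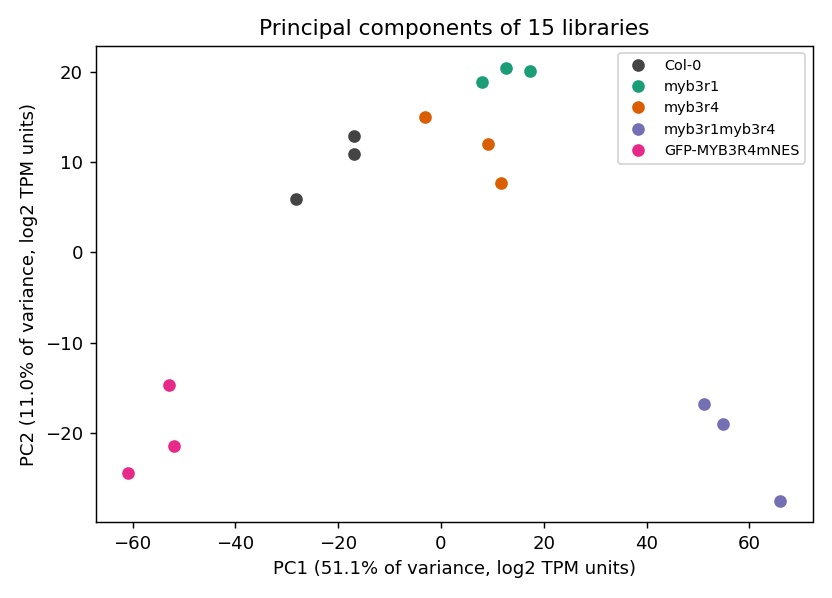
Principal components 1 (51.1% of the variance) and 2 (11.0%) of the log2 TPM values, 1 point per library, coloured by group. The mNES line and the double mutant lie at the ends of component 1, and myb3r1 and myb3r4 overlap on it.

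The comparison of myb3r1 with Col-0 asks which transcripts differ in the line labelled as mutant for MYB3R1 alone. MRD1 (AT1G53480) fell by 6.08 from a Col-0 mean of 45.7 TPM to 0.191 TPM (SE 0.15, limma adjusted p = 3.41e-11, n = 3 per group). Because 0.5 was added to each TPM, fold changes of genes near 0 TPM are smaller than the ratio of the TPM printed. Its overlapping neighbour HEI10 (AT1G53490), known for a role in meiotic crossovers, fell by 1.70; reads that the pair shares make either value uncertain. Also lower were LCR11 (AT4G11485) at -4.68, a member of a family of cysteine-rich peptides, RALFL26 (AT3G25170) at -3.74, a rapid alkalinization factor, and AT3G26860, of the family of S1 self-incompatibility proteins, at -3.77. AT1G60740, of the thioredoxin superfamily, fell too, with a value of -3.72. In the other direction, the uncharacterized gene AT5G35935 rose by 3.96 (SE 0.093) from 0.0114 to 7.44 TPM, and ACD6 (AT4G14400), which acts in salicylic acid signalling, rose by 1.22. In all, 1360 genes changed, 687 higher and 673 lower, or 6.26% of those tested. With median-of-ratios scaling 586 were higher and 733 lower, and with only the groups compared 601 and 854. Of the 1360, 17 rose and 232 fell at least 2-fold. The count was 662 without Col-0 replicate 2, 804 without Col-0 replicate 3, and 796, 880 and 757 without myb3r1 replicates 1, 2 and 3.

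In the photosynthesis list of the myb3r1 libraries, 2 of 12 measured members rose, 6 fell and 4 did not pass, and 2 were higher and 7 lower when adjusted over the list alone (camera adjusted p = 0.000108, and adjusted p = 0.475 with an estimated correlation). LHCA1 (AT3G54890) had a change of -0.66 and LHCB3 (AT5G54270) of -0.65. Of the clock list, 0 of 7 measured members rose, 3 fell and 4 did not pass, and 0 were higher and 4 lower when adjusted over the list alone (camera adjusted p = 1.86e-05, and adjusted p = 0.132 with an estimated correlation). PRR7 (AT5G02810) was at -0.54 and GI (AT1G22770) at -0.41. DNA replication genes went up slightly as a list (median 0.12), although 2 of 21 measured members rose, 0 fell and 19 did not pass, and 5 were higher and 0 lower when adjusted over the list alone (camera adjusted p = 0.000286, and adjusted p = 0.475 with an estimated correlation). Histone H4 genes, copies so similar that they share reads, had a median of 0.14 with 1 higher and 0 lower of 8, or 5 and 0 when adjusted over the list alone (camera adjusted p = 0.00215, and adjusted p = 0.565 with an estimated correlation). Among mitotic regulators, 5 of 18 measured members rose, 0 fell and 13 did not pass, and 7 were higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.0356, and adjusted p = 0.699 with an estimated correlation). SCL28 (AT1G63100), a transcription factor of the G2 and M phases, was at 0.41 and CDC20.2 (AT4G33260), an activator of the anaphase-promoting complex with a near-identical neighbour that shares its reads, at 0.39. The list call was lost on leaving out a library, with adjusted p = 0.117 without Col-0 replicate 2. Of the wounding and jasmonate genes, 0 of 15 measured members rose, 2 fell and 13 did not pass, and 0 were higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.00215, and adjusted p = 0.56 with an estimated correlation), a call lost with adjusted p = 0.0641 without Col-0 replicate 2. D-type cyclins had 2 higher and 1 lower of 10, or 3 and 1 when adjusted over the list alone (camera adjusted p = 0.0372, and adjusted p = 0.475 with an estimated correlation). CYCD7;1 (AT5G02110), a cyclin of the guard cell lineage, was at -1.47. The anther and tapetum list had 1 higher and 0 lower of 15 and a median of 0.21 (camera adjusted p = 0.0408, and adjusted p = 0.703 with an estimated correlation). The call of the D-type cyclins was lost with adjusted p = 0.0641 without Col-0 replicate 2, 0.105 without Col-0 replicate 3, 0.0847 without myb3r1 replicate 1 and 0.0871 without myb3r1 replicate 2. That of the anther list was lost with adjusted p = 0.117 without Col-0 replicate 2, 0.105 without Col-0 replicate 3, 0.0847 without myb3r1 replicate 1 and 0.163 without myb3r1 replicate 3. Mitotic cyclins were not called, with 0 higher and 2 lower of 18 (adjusted p = 0.9) and CYCA1;1 (AT1G44110) at -0.43, nor were the cytokinesis genes, with 4 higher and 0 lower of 18 (adjusted p = 0.391).

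The comparison of myb3r4 with Col-0 asks which transcripts differ in the line labelled as mutant for MYB3R4 alone. Several genes of cell division fell. KN (AT1G08560), the syntaxin that fuses vesicles at the cell plate, fell by 0.85 (SE 0.058, limma adjusted p = 1.29e-06, n = 3 per group) from 94.1 to 52.1 TPM. The B-type cyclins CYCB2;1 (AT2G17620) and CYCB2;2 (AT4G35620) had changes of -0.75 and -0.71. The receptor-like kinase gene IMK2 (AT3G51740) was at -1.94, ENODL15 (AT4G31840) at -1.29 and AT5G55180, which encodes a glycosyl hydrolase, at -1.77. Among the largest losses were MRD1 at -5.60, AT3G42725 at -3.69, AT1G04425 at -3.64 (SE 0.176) and AT3G05152 at -2.94. Among the largest gains were AT5G35935 at 3.87, AT5G52760, of a family of copper transport proteins, at 3.26 (SE 0.32), AT5G51190 at 3.09 and AT1G35210 at 2.99. In all, 1650 genes changed, 989 higher and 661 lower, or 7.59% of those tested, with 74 higher and 116 lower at least 2-fold. With only the groups compared the count was 765, 427 higher and 338 lower, and with upper-quartile scaling 827 were higher and 813 lower. The count was 904 and 903 without Col-0 replicates 1 and 2 and 863 and 831 without myb3r4 replicates 1 and 2.

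The mitotic lists of the myb3r4 libraries held changes in both directions, and none of them was called as a list. Of the mitotic cyclins and B-type CDKs, 2 of 18 measured members rose, 3 fell and 13 did not pass, and 4 were higher and 4 lower when adjusted over the list alone (camera adjusted p = 0.697), with CYCB1;4 (AT2G26760) at -0.50 besides CYCB2;1 and CYCB2;2. Of the mitotic regulators, 2 of 18 measured members rose, 4 fell and 12 did not pass, and 2 were higher and 5 lower when adjusted over the list alone (adjusted p = 0.756), and those lower included CDC20.2 at -0.50, SCL28 at -0.41 and the spindle checkpoint gene MAD2 (AT3G25980) at -0.36. Of the cytokinesis genes, 1 of 18 measured members rose, 4 fell and 13 did not pass, and 3 were higher and 4 lower when adjusted over the list alone (adjusted p = 0.971). Those lower were KN, EDE1 (AT2G44190), a microtubule-binding protein of the spindle and phragmoplast, at -0.50, CSLD5 (AT1G02730), which acts at the cell plate, at -0.40 and PATL4 (AT1G30690) at -0.36. Histone H4 genes were higher as a list, with 6 higher and 0 lower of 8, or 8 and 0 when adjusted over the list alone, and a median of 0.24 (camera adjusted p = 8.8e-06, and adjusted p = 0.357 with an estimated correlation). The annotated process of nucleosome assembly had 22 of 53 genes among those higher (Fisher's exact test, adjusted p = 1.19e-12). That test treats genes as independent, and the H4 list itself was not called with an estimated correlation. DNA replication genes had a median of 0.09 with 0 higher and 0 lower of 21, or 0 and 0 when adjusted over the list alone (camera adjusted p = 0.0122, and adjusted p = 0.504 with an estimated correlation), and the list call was lost with adjusted p = 0.057 without Col-0 replicate 2. Photosynthesis genes were lower as a list (camera adjusted p = 0.000151, and adjusted p = 0.357 with an estimated correlation), with 2 higher and 7 lower of 12, or 3 and 7 when adjusted over the list alone, LHCB2.1 (AT2G05100) at -1.18 and LHCB3 at -0.85. The type-A response regulators (adjusted p = 0.0501) and the clock list (adjusted p = 0.0501) just missed the threshold. The former, with ARR7 (AT1G19050) at 0.40, was called with adjusted p = 0.038 without Col-0 replicate 2, 0.0383 without Col-0 replicate 3, 0.00982 without myb3r4 replicate 1 and 0.0482 without myb3r4 replicate 2. The clock list was called with adjusted p = 0.0104 without Col-0 replicate 1, 0.0436 without myb3r4 replicate 1 and 0.0482 without myb3r4 replicate 2, and PRR7 was at -0.62 and GI at -0.44. Meristem regulators had 4 higher and 0 lower of 21 and were not called (adjusted p = 0.109).

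The comparison of the double mutant with Col-0 asks what differs in the line labelled as mutant for both genes. Many genes of cell division changed, in opposite directions. KN fell by 1.54 (SE 0.058, limma adjusted p = 8.93e-10, n = 3 per group) to 32.1 TPM, and CYCB2;1 (-1.10), SCL28 (-1.04) and CYCB2;2 (-0.73) were lower too. CYCB1;1 (AT4G37490), another B-type cyclin, rose by 0.77 (SE 0.073, adjusted p = 5.16e-06), the spindle checkpoint gene BUBR1 (AT2G33560) by 0.95 and 3xHMG-box2 (AT4G23800), whose protein binds mitotic chromosomes, by 0.82. Among the largest gains, BGL2 (AT3G57260), a glucanase of the salicylic acid response, rose by 5.57 (SE 0.19) from 0.407 to 42.9 TPM, the chitinase genes CHI (AT2G43570) by 4.93, AT2G43590 by 4.17 and AT2G43620 by 3.75, and PNP-A (AT2G18660) by 3.75. Among the largest losses were MRD1 at -6.07, the defensin-like gene AT5G60615 at -5.79, LCR11 at -5.35, AT1G04425 at -5.11, RALFL20 (AT2G34825) at -4.82 (SE 1.03), AT3G26860 at -4.60 and AT3G59765 at -4.29. In all, 9037 genes changed, 5321 higher and 3716 lower, or 41.6% of those tested, and 343 rose and 1032 fell at least 2-fold. Of the calls, 58.9% were higher, against 45.4% with median-of-ratios scaling (3813 higher and 4578 lower).

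The mitotic and S-phase lists were mostly higher in the double mutant. Of the mitotic cyclins and B-type CDKs, 12 of 18 measured members rose, 3 fell and 3 did not pass, and 12 were higher and 3 lower when adjusted over the list alone (camera adjusted p = 0.0161, and adjusted p = 0.339 with an estimated correlation). CDKB1;1 (AT3G54180) was at 0.68, and the 3 lower members were CYCB2;1, CYCB2;2 and CYCB1;4, at -0.37. Of the mitotic regulators, 13 of 18 measured members rose, 4 fell and 1 did not pass, and 13 were higher and 4 lower when adjusted over the list alone (camera adjusted p = 0.0305, and adjusted p = 0.419 with an estimated correlation). The kinesin gene ATK5 (AT4G05190) was at 0.69 and CDC20.2 at -0.42. The list call was lost with adjusted p = 0.0551 without myb3r1myb3r4 replicate 3. Of the cytokinesis genes, 13 of 18 measured members rose, 4 fell and 1 did not pass, and 14 were higher and 4 lower when adjusted over the list alone (camera adjusted p = 0.0128, and adjusted p = 0.29 with an estimated correlation). KIN12B (AT3G23670), a kinesin of the phragmoplast, was at 0.63, MAP65-3 (AT5G51600), which bundles its microtubules, at 0.51, PATL4 at -0.49 and EDE1 at -0.28. DNA replication genes went one way, as 16 of 21 measured members rose, 0 fell and 5 did not pass, and 18 were higher and 0 lower when adjusted over the list alone (camera adjusted p = 2.46e-06, and adjusted p = 0.267 with an estimated correlation). The helicase subunit gene MCM6 (AT5G44635) was at 0.48 and PCNA2 (AT2G29570), a sliding clamp, at 0.47. All histone H4 genes rose, 8 of 8, with a median of 0.56 (camera adjusted p = 9.08e-06, and adjusted p = 0.267 with an estimated correlation). D-type cyclins had 6 higher and 1 lower of 10, or 7 and 1 when adjusted over the list alone (camera adjusted p = 0.0439, and adjusted p = 0.291 with an estimated correlation). CYCD7;1 was at -2.36, and the list call was lost with adjusted p = 0.085 without Col-0 replicate 3, 0.0567 without myb3r1myb3r4 replicate 1 and 0.0551 without myb3r1myb3r4 replicate 3. Of the CDK inhibitors, 4 of 13 measured members rose, 3 fell and 6 did not pass, and 4 were higher and 3 lower when adjusted over the list alone (adjusted p = 0.72). Their median of 0.03 turned to -0.02 with median-of-ratios scaling, and SMR2 (AT1G08180) was at -0.88. MYB3R, E2F and DREAM components had 8 higher and 0 lower of 15, or 9 and 0 when adjusted over the list alone (camera adjusted p = 0.0161, and adjusted p = 0.29 with an estimated correlation).

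**Figure D3:**
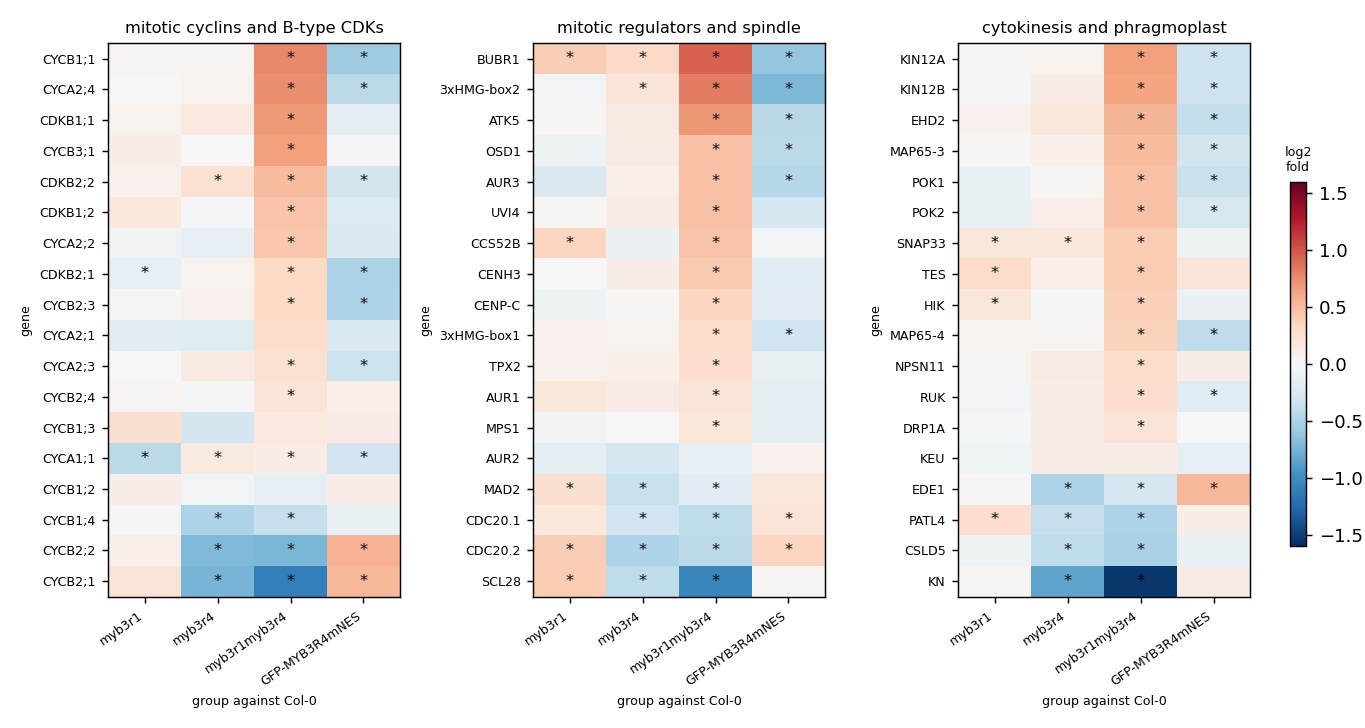
Heat maps of log2 fold changes against Col-0 for the members of the 3 mitotic lists (rows) in the 4 other groups (columns), with stars at adjusted p under 0.05. In the double mutant 38 of 54 members were higher and 11 lower; KN, at -1.54, was the lowest.

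Cytokinin feedback genes, vascular genes and photosynthesis genes were lower in the double mutant, and meristem and floral genes changed in both directions. Among the type-A response regulators, which repress cytokinin signalling, 0 of 8 measured members rose, 5 fell and 3 did not pass, and 0 were higher and 5 lower when adjusted over the list alone (camera adjusted p = 0.0192, and adjusted p = 0.267 with an estimated correlation). ARR15 (AT1G74890) was at -0.54 (SE 0.143) and ARR9 (AT3G57040) at -0.49. Cytokinin signalling genes had 6 higher and 0 lower of 16, or 6 and 0 when adjusted over the list alone, among them ARR10 (AT4G31920) at 0.48, without a call (adjusted p = 0.213). Cytokinin synthesis and degradation genes had 3 higher and 4 lower of 13, or 3 and 4 when adjusted over the list alone (adjusted p = 0.533), with the cytokinin oxidase gene CKX3 (AT5G56970) at -0.95. Importins and exportins were higher, with 8 higher and 0 lower of 11, or 10 and 0 when adjusted over the list alone, IMPA6 (AT1G02690) at 0.51 and XPO1A (AT5G17020) at 0.26 (camera adjusted p = 0.0128, and adjusted p = 0.267 with an estimated correlation). Of the meristem regulators, 8 of 21 measured members rose, 2 fell and 11 did not pass, and 9 were higher and 2 lower when adjusted over the list alone (adjusted p = 0.0975). WUS (AT2G17950), which maintains stem cells, was at -0.62 (SE 0.136), and the organ boundary genes CUC1 (AT3G15170) and CUC2 (AT5G53950) were at 0.76 and 0.75. Floral identity genes had 8 higher and 4 lower of 16, or 8 and 5 when adjusted over the list alone (adjusted p = 0.52), with LFY (AT5G61850), the regulator of flower identity, at 1.19 (SE 0.147), SEP1 (AT5G15800) at 0.38 and SEP3 (AT1G24260) at -0.39. The vascular list had 0 higher and 7 lower of 9, or 0 and 7 when adjusted over the list alone (camera adjusted p = 0.000325, and adjusted p = 0.267 with an estimated correlation). The cellulose synthase genes of secondary walls were CESA4 (AT5G44030) at -0.84, CESA7 (AT5G17420) at -0.77 and CESA8 (AT4G18780) at -0.87. Photosynthesis genes had 1 higher and 10 lower of 12, or 1 and 11 when adjusted over the list alone (camera adjusted p = 2.42e-07, and adjusted p = 0.267 with an estimated correlation). LHCB2.1 was at -0.81.

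In the double mutant, of the anther and tapetum list, 11 of 15 measured members rose, 1 fell and 3 did not pass, and 12 were higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.0128, and adjusted p = 0.419 with an estimated correlation). LAP5 (AT4G34850), which makes precursors of the pollen wall, was at 1.02 and AMS (AT2G16910), a tapetum regulator, at 0.74, while the lower member GRP17 (AT5G07530) was at -1.06. Meiosis genes had 9 higher and 1 lower of 13, or 9 and 1 when adjusted over the list alone (camera adjusted p = 0.0427, and adjusted p = 0.302 with an estimated correlation). ASY1 (AT1G67370) was at 0.68. DNA damage genes had 4 higher and 0 lower of 12, or 4 and 0 when adjusted over the list alone (camera adjusted p = 0.0257, and adjusted p = 0.29 with an estimated correlation). BRCA1 (AT4G21070) was at 0.45. Wounding and jasmonate genes had 8 higher and 1 lower of 15, or 9 and 1 when adjusted over the list alone (camera adjusted p = 0.0439, and adjusted p = 0.419 with an estimated correlation). VSP1 (AT5G24780) was at 0.66, OPR3 (AT2G06050) at 0.48 and the lower member JAZ7 (AT2G34600) at -2.01. Heat shock genes had 3 higher and 0 lower of 5, or 3 and 0 when adjusted over the list alone, with HSP70 (AT3G12580) at 0.88 (adjusted p = 0.0975), and clock genes had 1 higher and 3 lower of 7, or 1 and 3 when adjusted over the list alone (adjusted p = 0.199). The meiosis call was lost with adjusted p = 0.0677 without myb3r1myb3r4 replicate 1 and 0.0532 without myb3r1myb3r4 replicate 3, the DNA damage call with 0.0517 without myb3r1myb3r4 replicate 1 and the wounding call with 0.143 without Col-0 replicate 1, 0.0897 without myb3r1myb3r4 replicate 1 and 0.0643 without myb3r1myb3r4 replicate 2. Among annotated processes, nucleosome assembly had 41 of 53 genes among those higher (Fisher's exact test, adjusted p = 3.77e-12), and protein catabolism through ubiquitin had 81 of 139 (adjusted p = 2.06e-12). Defence response had 81 of 224 (Fisher's exact test, adjusted p = 0.0396) and response to salicylic acid 12 of 20 (adjusted p = 0.0301). Photosynthesis had 51 of 66 genes among those lower (Fisher's exact test, adjusted p = 1.57e-22). The tests of processes treat genes as independent. They were not repeated with median-of-ratios scaling, where 3813 genes rather than 5321 were higher.

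**Figure D4:**
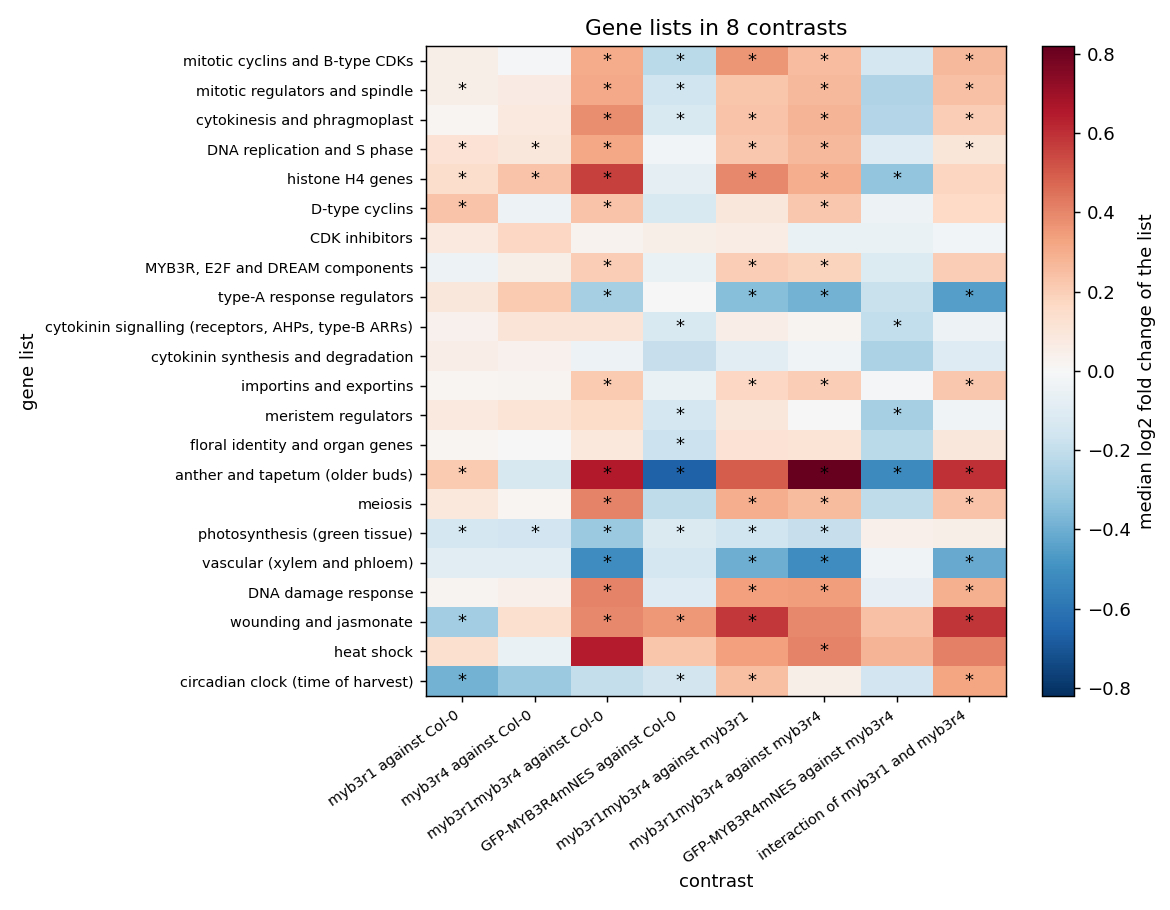
Median log2 fold change of each of the 22 gene lists (rows) in each of the 8 contrasts (columns), with stars where camera gave an adjusted p under 0.05. The anther and tapetum list runs from 0.65 in the double mutant to -0.67 in the mNES line.

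The comparison of the mNES line with Col-0 asks what differs in the line labelled with a GFP-tagged form of MYB3R4. The background of the line is not stated, so the differences cannot be assigned to the transgene alone. The cyclins CYCB2;1 and CYCB2;2 rose while other mitotic genes fell. CYCB2;2 rose by 0.56 (SE 0.059, limma adjusted p = 7.03e-05, n = 3 per group), CYCB2;1 by 0.54 and EDE1 by 0.53. 3xHMG-box2 changed by -0.72 (adjusted p = 1.9e-06), BUBR1 by -0.62, CYCB1;1 by -0.57, CDKB2;1 (AT1G76540) by -0.51 and ATK5 by -0.44. Among the largest gains were AT2G45780 at 4.85, AT3G05152 at 3.19, AT3G59765 at 2.74, AT1G04425 at 2.63 and AT3G42725 at 2.45. Those lower included AT2G30766 at -2.65, AT1G47400 at -1.72, MYBL2 (AT1G71030), a MYB repressor, at -1.53, DREB1A (AT4G25480), a regulator of the cold response, at -1.48 and ACD6 at -1.32. In all, 3695 genes changed, 1653 higher and 2042 lower, or 17.0% of those tested, with 392 higher and 47 lower at least 2-fold. Of the calls 44.7% were higher, against 59.5% with median-of-ratios scaling (2191 higher and 1491 lower). With only the groups compared the count was 2078, 1121 higher and 957 lower.

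As lists, mitotic, meristem, floral and anther genes were lower in the mNES line. Of the mitotic cyclins and B-type CDKs, 2 of 18 measured members rose, 7 fell and 9 did not pass, and 2 were higher and 9 lower when adjusted over the list alone (camera adjusted p = 0.0126, and adjusted p = 0.471 with an estimated correlation). Of the mitotic regulators, 2 of 18 measured members rose, 6 fell and 10 did not pass, and 3 were higher and 10 lower when adjusted over the list alone (camera adjusted p = 0.0117, and adjusted p = 0.471 with an estimated correlation). Of the cytokinesis genes, 1 of 18 measured members rose, 8 fell and 9 did not pass, and 3 were higher and 9 lower when adjusted over the list alone (camera adjusted p = 0.0369, and adjusted p = 0.471 with an estimated correlation). KIN12B was at -0.33 and MAP65-3 at -0.29. The calls were lost with adjusted p = 0.0663 without GFP-MYB3R4mNES replicate 1 for the cyclins, 0.0653 without GFP-MYB3R4mNES replicate 1 for the regulators and 0.0587 without Col-0 replicate 2, 0.0653 without GFP-MYB3R4mNES replicate 1 and 0.0597 without GFP-MYB3R4mNES replicate 3 for the cytokinesis genes. Meristem regulators had 0 higher and 5 lower of 21, or 0 and 10 when adjusted over the list alone (camera adjusted p = 0.0117, and adjusted p = 0.416 with an estimated correlation). ULT1 (AT4G28190) was at -0.33 and HAM1 (AT2G45160) at -0.32. Floral identity genes had 2 higher and 8 lower of 16, or 3 and 9 when adjusted over the list alone (camera adjusted p = 0.0117, and adjusted p = 0.416 with an estimated correlation). LFY was at -0.65, SEP2 (AT3G02310) at -0.52 and AP1 (AT1G69120) at -0.31. Anther and tapetum genes had 0 higher and 11 lower of 15, or 0 and 14 when adjusted over the list alone, and a median of -0.67 (camera adjusted p = 1.42e-05, and adjusted p = 0.416 with an estimated correlation). LAP5 was at -0.85, LAP6 (AT1G02050) at -0.85 and MS1 (AT5G22260) at -0.80. The annotated process of pollen exine formation had 7 of 10 genes among those lower (Fisher's exact test, adjusted p = 0.000249).

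In the mNES line, wounding and jasmonate genes had 7 higher and 1 lower of 15, or 7 and 3 when adjusted over the list alone (camera adjusted p = 0.0117, and adjusted p = 0.471 with an estimated correlation). VSP1 was at 0.53, LOX2 (AT3G45140) at 0.45 and JAZ5 (AT1G17380) at 0.68. The call was lost with adjusted p = 0.249 without Col-0 replicate 1. Photosynthesis genes had 2 higher and 6 lower of 12, or 2 and 7 when adjusted over the list alone (camera adjusted p = 0.0117, and adjusted p = 0.487 with an estimated correlation). LHCB2.1 was at -0.74 and LHCB3 at -0.59, and the call was lost with adjusted p = 0.0707 without Col-0 replicate 2. Clock genes had 0 higher and 2 lower of 7, or 0 and 4 when adjusted over the list alone (camera adjusted p = 0.0342, and adjusted p = 0.416 with an estimated correlation). PRR7 was at -0.32. The call was lost with adjusted p = 0.0707 without Col-0 replicate 2, 0.064 without Col-0 replicate 3 and 0.0597 without GFP-MYB3R4mNES replicate 3. In myb3r1, myb3r4, the double mutant and the mNES line, medians were -0.389, -0.304, -0.195 and -0.148 for clock genes. For photosynthesis genes they were -0.142, -0.16, -0.302 and -0.121. All these contrasts share the Col-0 libraries, so the falls are not separate evidence. The clock list was included for the time of harvest, whose part was not tested. Cytokinin signalling genes had 0 higher and 4 lower of 16, or 0 and 4 when adjusted over the list alone (camera adjusted p = 0.0377, and adjusted p = 0.416 with an estimated correlation). ARR1 (AT3G16857) was at -0.26 and AHK2 (AT5G35750) at -0.24. The call was lost with adjusted p = 0.0719 without Col-0 replicate 2, 0.106 without Col-0 replicate 3, 0.0549 without GFP-MYB3R4mNES replicate 2 and 0.0665 without GFP-MYB3R4mNES replicate 3. Not called were histone H4 genes (adjusted p = 0.248, but 0.00797 without GFP-MYB3R4mNES replicate 3), meiosis genes (0.172, but 0.0372 without GFP-MYB3R4mNES replicate 3) and heat shock genes (0.0949, but 0.0395 without Col-0 replicate 1). DNA replication genes were not called either (0.761), and their median, near 0, changed sign with median-of-ratios scaling. Importins and exportins had 0 higher and 2 lower of 11, or 0 and 2 when adjusted over the list alone (adjusted p = 0.517), with IMPA6 at -0.37.

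The double mutant was compared with each single mutant to ask what the second mutation adds. Against myb3r1, the strongest losses included IMK2 at -2.58 (SE 0.053), AT5G55180 at -2.38, AT3G02640 at -2.29 and ENODL15 at -2.03 (limma, n = 3 per group). The strongest gains included BGL2 at 5.55, AT5G10760, an aspartyl protease gene, at 2.93 and AOC3 (AT3G25780), an enzyme of jasmonate synthesis, at 2.07. Against myb3r4, AT5G16250 changed by -1.19, AT3G02640 by -1.84, AT2G42110 by -1.28 and BGL2 by 4.28, with DMR6 (AT5G24530), which degrades salicylic acid, at 1.38. Against myb3r1, 6550 genes changed (3743 higher and 2807 lower), and against myb3r4, 7544 (4365 higher and 3179 lower). The shares higher were 57.1% and 57.9%, against 44.1% (2743 higher and 3477 lower) and 44.9% (3171 higher and 3889 lower) with median-of-ratios scaling.

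The type-A response regulators were lower against both single mutants. Against myb3r4 they had 0 higher and 8 lower of 8 (camera adjusted p = 0.00014, and adjusted p = 0.0945 with an estimated correlation), and ARR15 was at -0.81. Against myb3r1 they had 0 higher and 5 lower of 8 (camera adjusted p = 0.00183, and adjusted p = 0.243 with an estimated correlation). Histone H4 genes were higher against both, with 8 higher and 0 lower of 8 against myb3r1 (camera adjusted p = 5.43e-05, and adjusted p = 0.249 with an estimated correlation) and 7 higher and 0 lower of 8 against myb3r4 (camera adjusted p = 0.000513, and adjusted p = 0.239 with an estimated correlation). DNA replication genes had 13 higher and 0 lower of 21 against myb3r1 (camera adjusted p = 0.00013, and adjusted p = 0.249 with an estimated correlation) and 16 higher and 0 lower of 21 against myb3r4 (camera adjusted p = 6.58e-05, and adjusted p = 0.22 with an estimated correlation). For mitotic cyclins the members were 13 higher and 4 lower of 18 against myb3r1 (camera adjusted p = 0.00559, and adjusted p = 0.279 with an estimated correlation). Against myb3r4 they were 12 higher and 0 lower of 18 (camera adjusted p = 0.000513, and adjusted p = 0.23 with an estimated correlation). KN, of the cytokinesis list, was at -1.56 against myb3r1. The vascular list had 0 higher and 6 lower of 9 against myb3r1 (camera adjusted p = 0.000358, and adjusted p = 0.243 with an estimated correlation) and 0 higher and 6 lower of 9 against myb3r4 (camera adjusted p = 0.000825, and adjusted p = 0.22 with an estimated correlation). Wounding and jasmonate genes had 12 higher and 0 lower of 15 against myb3r1 (camera adjusted p = 0.00015, and adjusted p = 0.249 with an estimated correlation), and anther genes 12 higher and 1 lower of 15 against myb3r4 (camera adjusted p = 0.000513, and adjusted p = 0.314 with an estimated correlation). Not called were wounding and jasmonate genes against myb3r4, with 4 higher and 1 lower of 15 (adjusted p = 0.0952, but 0.0243 without myb3r4 replicate 3 and 0.0342 without myb3r1myb3r4 replicate 3), and anther genes against myb3r1, with 6 higher and 2 lower of 15 (adjusted p = 0.0859).

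The mNES line was compared with myb3r4 because the transgene carries the gene that this mutant is named for; the background of the line is not stated, so only the labels are compared. Several genes that fell in myb3r4 were higher in the mNES line. IMK2 was higher by 2.85 (SE 0.053), AT5G55180 by 1.90, ENODL15 by 1.71, CYCB2;2 by 1.27 and KN by 0.96 (limma, n = 3 per group). AT1G04425 differed by 6.27 and MRD1 by 5.47. 3xHMG-box2 was at -0.92 and AT5G35935 at -3.84. In all, 6404 genes changed, 2522 higher and 3882 lower. The share higher was 39.4%, against 54.6% with median-of-ratios scaling (3376 higher and 2805 lower). All histone H4 genes were lower, 8 of 8 (camera adjusted p = 0.000489, and adjusted p = 0.605 with an estimated correlation). Meristem regulators had 1 higher and 13 lower of 21 (camera adjusted p = 0.00325, and adjusted p = 0.205 with an estimated correlation). Cytokinin signalling genes had 0 higher and 6 lower of 16 (camera adjusted p = 0.00489, and adjusted p = 0.205 with an estimated correlation), and anther genes 0 higher and 10 lower of 15 (camera adjusted p = 0.00615, and adjusted p = 0.661 with an estimated correlation). The anther call was lost with adjusted p = 0.0762 without GFP-MYB3R4mNES replicate 1.

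The interaction asks whether the effect of myb3r4 differs between the wild-type and the myb3r1 background. A positive value means that the double mutant lay above the sum of the single effects, and a negative value that it lay below. AT5G16250 had a value of -1.33 (SE 0.057, limma adjusted p = 2.97e-08, n = 3 per group), AT3G02640 of -1.98, SCL28 of -1.04 and KN of -0.71. Positive values were found for BGL2 at 4.26, CYCB1;1 at 0.68 and LFY at 1.07. Genes that were as low or as high in both single mutants as in the double mutant had values of the opposite sign, such as MRD1 at 5.61 and AT5G35935 at -3.69. MRD1 stood near 0 TPM in all 3 of them, so its value is set by the floor that the added 0.5 makes and does not measure how the effects combine. In all, 2665 genes had an interaction, 1371 positive and 1294 negative, against 1141 positive and 1609 negative with median-of-ratios scaling. The type-A response regulators had a median of -0.45 with 0 higher and 4 lower of 8 (0 and 8 when adjusted over the list alone; camera adjusted p = 2.27e-05, and adjusted p = 0.0463 with an estimated correlation), the only list call of the interaction that held with an estimated correlation. Mitotic cyclins had 8 higher and 0 lower of 18 and a median of 0.26 (camera adjusted p = 0.000199, and adjusted p = 0.26 with an estimated correlation), and cytokinesis genes 7 higher and 2 lower of 18 (camera adjusted p = 0.00629, and adjusted p = 0.26 with an estimated correlation). Wounding and jasmonate genes had 5 higher and 0 lower of 15 (camera adjusted p = 0.00267, and adjusted p = 0.301 with an estimated correlation) and clock genes 2 higher and 0 lower of 7 (camera adjusted p = 0.00284, and adjusted p = 0.26 with an estimated correlation). Clock genes had medians below Col-0 in every other group. Col-0 enters the interaction with a plus sign, so Col-0 libraries that stand high for this list would give a positive value too.

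The MSA element was searched in promoters because MYB3R proteins bind it. Of the genes lower in myb3r4, 59 of 656 had it (8.99%), against 3.35% of all other tested genes (odds ratio 2.85, Fisher's exact test, adjusted p = 3.53e-10). Genes higher in the mNES line had it in 98 of 1641 cases (5.97% against 3.32%, odds ratio 1.85, adjusted p = 8.24e-07), and those higher in myb3r1 in 43 of 682 (6.30% against 3.43%, odds ratio 1.89, adjusted p = 0.000744). Genes higher in the double mutant had an odds ratio of 1.22 (215 of 5301, adjusted p = 0.0324), which was 1.129 with adjusted p = 0.135 in a window of 1000 bases, and those lower one of 1.20 (150 of 3686, adjusted p = 0.0793). The sets lower in myb3r1 (odds ratio 0.970), higher in myb3r4 (1.07) and lower in the mNES line (1.103) did not pass the test. Of the genes lower in myb3r4, 178 were higher in the mNES line, where 50.3 would be shared by independent lists; 26 of 177 with a promoter had the element (14.7% against 3.43%, odds ratio 4.85, Fisher's exact test, p = 7.09e-10). Without the 99 of them that were also lower in myb3r1, 23 of 79 had it (29.1%, odds ratio 11.6, Fisher's exact test, p = 2.04e-15). Of the genes higher in myb3r4 and lower in the mNES line, 7 of 121 had it (odds ratio 1.69, Fisher's exact test, p = 0.206). These sets were defined after the data were seen. With only the core of the element no set passed the test.

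**Figure D5:**
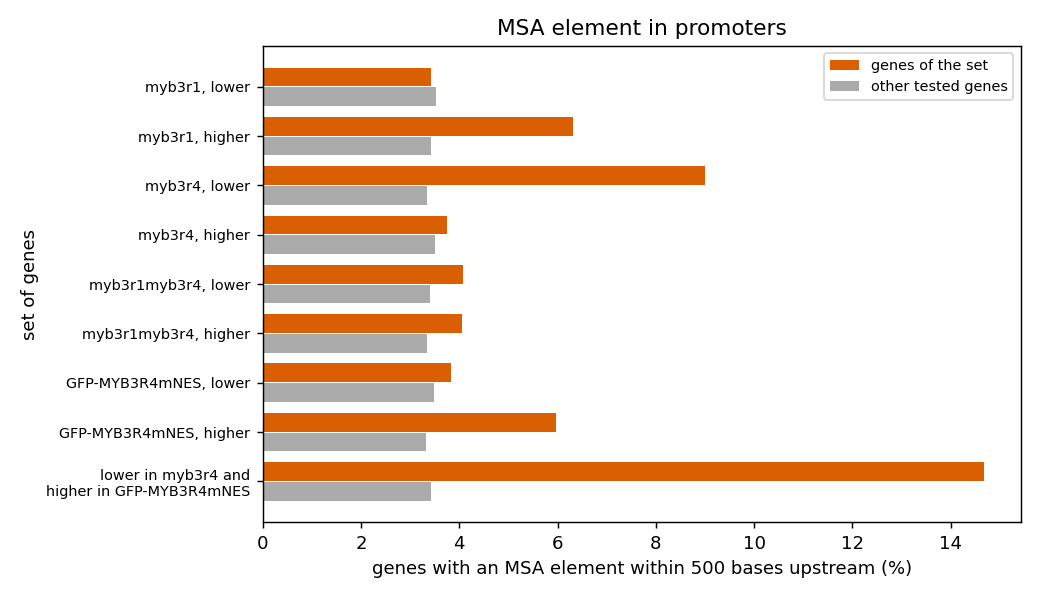
Percent of genes with an MSA element within 500 bases upstream, for genes lower and higher than in Col-0 in each comparison. A last set, defined after the data were seen, holds genes lower in myb3r4 and higher in the mNES line. Beside each set stand all other tested genes, and bars start at 0. The last set stands highest, 14.7% against 3.43%. Among the other sets, the genes lower in myb3r4 stand highest, 8.99% against 3.35%.

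Fold changes against Col-0 were compared between contrasts across genes, which are not independent replicates, and contrasts with the same controls correlate without any effect. The myb3r1 and myb3r4 contrasts had r = 0.62, against 0.50 in simulations with unchanged groups, and a covariance of 0.0626 against 0.0155. Those of myb3r1 and the double mutant had r = 0.67 (simulated 0.50, covariance 0.128 against 0.0155), and those of myb3r4 and the double mutant r = 0.64 (simulated 0.50, covariance 0.114 against 0.0154). For myb3r1 and myb3r4, 285 genes were higher and 286 lower in both, where independent lists would share 31.3 and 20.5. The simulations gave 0, but no gene changed in them, so this was all but fixed in advance and is no measure for the overlaps. For myb3r1 and the double mutant 467 genes were higher and 556 lower in both (independent 168 and 115). For myb3r4 and the double mutant 699 were higher and 477 lower in both (independent 242 and 113). The 3 Col-0 libraries cannot be split into separate controls of 2 or more for each contrast, so part of this excess may come from the shared controls. The mNES contrast correlated with that of the double mutant with r = -0.29 (simulated 0.50, covariance -0.0600), with 690 genes lower in the double mutant and higher in the mNES line and 798 the other way, where independent lists would share 283 and 500. With the contrast of myb3r1 its r was -0.24 (simulated 0.50, covariance -0.0280) and with that of myb3r4 -0.10 (simulated 0.50, covariance -0.0113). The r with myb3r1 was -0.113 and -0.157 without Col-0 replicates 1 and 2, and that with myb3r4 was -0.043, 0.018 and -0.037 without Col-0 replicates 1, 2 and 3.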

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

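The interaction contrast, its lists and the regroupings of the libraries were planned, and the tests of the mitotic genes that close this part were chosen only after the result was seen. The effect of myb3r4 differed between the wild-type and the myb3r1 background for 2665 genes (1371 positive and 1294 negative, but 1141 and 1609 with median-of-ratios scaling). Of 100 regroupings of the 12 libraries, the real one included, 2 gave as many genes, and the highest of the others gave 3658. A regrouping mixes libraries of groups that differ, such as the double mutant and Col-0, so those differences can enter its interaction count. The regroupings therefore do not decide on chance for the interaction. For the 12160 genes that differed among the groups, 1 of 100 regroupings of the 15 libraries gave as many, the real one. The highest of the others gave 2348, which argued against chance for that count. Comparisons of 3 libraries with 3 have 10 splits, too few to decide on chance, and in each 1 of the 10 gave as many genes, the real one. The real count and the highest of the other splits were 1360 and 1 for myb3r1, 1650 and 1 for myb3r4, 9037 and 0 for the double mutant and 3695 and 5 for the mNES line against Col-0. They were 6550 and 1 for the double mutant against myb3r1, 7544 and 0 for the double mutant against myb3r4 and 6404 and 2 for the mNES line against myb3r4.

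The lists that camera called in the interaction were mostly higher. The medians were 0.26 for mitotic cyclins, 0.2 for cytokinesis genes, 0.22 for importins and exportins, 0.23 for meiosis genes, 0.59 for wounding and jasmonate genes and 0.32 for clock genes, against -0.45 for the type-A response regulators and -0.42 for vascular genes. The clock list had medians below Col-0 in every other group, so Col-0 libraries that stand high for it could give its positive value. Calls that rested on single libraries were those of the mitotic regulators (median 0.24, adjusted p = 0.0373; 0.0677 without Col-0 replicate 1, 0.0523 without myb3r1 replicate 3, 0.0663 without myb3r4 replicate 3 and 0.0928 without myb3r1myb3r4 replicate 3), DNA replication genes (median 0.1, adjusted p = 0.0293; 0.0677 without Col-0 replicate 1, 0.086 without myb3r4 replicate 3 and 0.0857 without myb3r1myb3r4 replicate 3), anther genes (median 0.6, adjusted p = 0.0213; 0.0551 without Col-0 replicate 1 and 0.072 without myb3r1myb3r4 replicate 3) and DNA damage genes (median 0.29, adjusted p = 0.0418; 0.0677 without Col-0 replicate 1, 0.074 without Col-0 replicate 3, 0.0679 without myb3r1 replicate 2, 0.0628 without myb3r4 replicate 3, 0.0653 without myb3r1myb3r4 replicate 1 and 0.0718 without myb3r1myb3r4 replicate 3). With an estimated correlation, the type-A response regulators alone were called among these lists (adjusted p = 0.0463).

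Among the genes named here, the test of the interaction itself gave these values on the log2 scale (limma, n = 3 per group). Of the targets, MYB3R1 was at -0.39 and MYB3R4 at 0.43. Mitotic genes below the sum of the single effects were KN at -0.71, SCL28 at -1.04, CDC20.2 at -0.31 and PATL4 at -0.39. Genes of mitosis and S phase above it were CYCB1;1 at 0.68, 3xHMG-box2 at 0.66, KIN12B at 0.57, ATK5 at 0.52, CDKB1;1 at 0.47, MAP65-3 at 0.42, CDKB2;1 at 0.39, CYCA1;1 at 0.39, MCM6 at 0.28 and PCNA2 at 0.22. Also above it were BGL2 at 4.26, AT2G43590 at 2.34, CHI at 2.02, AT2G43620 at 2.00, PNP-A at 1.56, AT5G10760 at 1.47, AOC3 at 1.01, DMR6 at 0.97, JAZ5 at 0.80, VSP1 at 0.55, OPR3 at 0.50 and HSP70 at 0.79. Regulators of flowers and transport above it were LFY at 1.07, AMS at 0.61, SEP2 at 0.27, IMPA6 at 0.37 and XPO1A at 0.27, and genes of cytokinin signalling, the cell cycle, anthers and cell walls below it were ARR15 at -0.96, ARR9 at -0.67, ARR7 at -0.36, SMR2 at -1.14, GRP17 at -0.71 and CESA4 at -0.64. Positive values were also found for MRD1 at 5.61, HEI10 at 1.81, LHCB1.1 (AT1G29920) at 2.23, LHCB2.1 at 1.37, LHCB3 at 0.96, LHCA1 at 0.88, PRR7 at 0.97, GI at 0.65, DREB1A at 1.92 and AT2G45780 at 1.01, and negative values for AT5G35935 at -3.69, AT3G29120 at -2.78, AT3G30160 at -1.79 and ACD6 at -1.56. MRD1 stood near 0 TPM in all 3 mutant-labelled groups, so its value is set by the floor of the log2 scale. The limit given above for the clock list holds for its members PRR7 and GI. The remaining negative values were AT3G59765 at -2.28, AT3G02640 at -1.98, AT2G42110 at -1.48, AT5G16250 at -1.33, AT1G04425 at -0.85, ENODL15 at -0.74, IMK2 at -0.64 and AT5G55180 at -0.61.

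Of 54 measured members of the mitotic lists, 38 were higher and 11 lower in the double mutant, and all 11 were also lower in myb3r4. A different share of dividing cells that moves all members one way would not lower these 11 while others rose. This count is the pattern itself, so it does not test a change that moves members apart. Median-of-ratios scaling moved log2 fold changes by about -0.050 in the double mutant. It could not undo the calls of the 11 lower members, all kept, but was small beside their median of -0.49. Of the higher ones 94.7% (36 of 38) kept their call, which argued against the normalization to TPM as their whole cause. A larger share of dividing cells may account for the higher members, as the DNA replication list, with a median of 0.32, and the histone H4 genes, with 0.56, rose too. These rises do not tell a larger share apart from a direct effect of the mutations that the labels name. For the lower members a role of the MSA element stays open, with 6 of 11 against 9 of 38 promoters (odds ratio 3.744, Fisher's exact test, p = 0.0693). A direct effect of the mutations stays open for the higher and the lower members, and these data do not test it.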

How the results depend on the processing

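The pseudocounts, the minimum TPM of 5, the scalings, the nuclear genes alone, and the correlations without a filter were chosen after seeing the data; the other alternatives were planned. The planned normalizations for counts were not run, because the values are TPM. Depth is unknown, so its limits could not be measured. Under pseudocounts, filters, scalings, nuclear genes alone and robust variances, all 8 counts of changed genes stayed within 1.5 times their value. With the groups compared alone, 765 genes changed in myb3r4 and 2078 in the mNES line against Col-0, with fewer samples behind each spread. At an adjusted p under 0.01 the counts were 505 for myb3r1, 527 for myb3r4, 1723 for the mNES line, 3883 and 4449 for the double mutant against myb3r1 and against myb3r4, 3692 for the mNES line against myb3r4 and 1068 for the interaction. With a fold change of at least 1 on the log2 scale added, they were 249 for myb3r1, 190 for myb3r4, 1375 for the double mutant, 439 for the mNES line, 796, 861 and 923 for the other 3 in the same order and 365 for the interaction. Both follow from the stricter threshold.

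Without single libraries, the counts were 662 to 1258 for myb3r1, 831 to 1476 for myb3r4, 7241 to 8305 for the double mutant, 2491 to 3349 for the mNES line, 4916 to 5827 and 5531 to 6822 for the double mutant against myb3r1 and against myb3r4, 4852 to 5880 for the mNES line against myb3r4, 1891 to 2517 for the interaction and 7329 to 8063 for the F test without 1 replicate number. Each has fewer samples. Correlations across genes were 0.611 to 0.671 for myb3r1 with myb3r4, 0.655 to 0.695 for myb3r1 and 0.613 to 0.67 for myb3r4 with the double mutant. With the mNES line they were -0.185 to -0.113 for myb3r1, -0.244 to -0.213 for the double mutant and -0.043 to 0.018 for myb3r4, the last reversed at 0.018 without Col-0 replicate 2; the cause was not tested. Without a filter these were -0.175, -0.241 and -0.047, and the cause was not tested.

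For the MSA element, the odds ratio of genes higher in the double mutant was 1.129 in 1000 bases. With the core of the element alone the odds ratios were 1.204 for genes higher in myb3r1, 1.241 for genes lower in myb3r4, 1.036 for genes higher in the double mutant and 1.092 for genes higher in the mNES line, none past the test; the cause was not tested. Of 176 list results, 79 lost their call with an estimated correlation, which left that of the type-A response regulators in the interaction, 8 with fry, which added 41, and 0 with median-of-ratios scaling, which added 4. Fry does not compare a list with other genes as camera does, so its counts do not test the camera calls. In list results where the median, the mean and the test differed in sign, no call was made. Without single libraries, 56 list results lost and 29 gained a call, and 1103 kept their side of the threshold. For named genes without single libraries, 186 results lost their call and 1752 did not; 6 lost it with median-of-ratios scaling and 7 without a filter.

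Residuals gave no sign that the replicate number, which equals the number of the shift experiment in the labels, pairs the libraries. Residuals of libraries with the same number correlated with r of -0.125 to 0.0885, and 3 of 15 libraries correlated best with one of their own number. With a replicate block, 1158 genes changed in myb3r1, 1396 in myb3r4, 8830 in the double mutant and 3444 in the mNES line, and 10 named genes lost their call.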

Other observations

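The pollen list, the set of genes changed alike and all tests of this part were chosen only after the result was seen. Listed transcripts of pollen and pollen tubes were mostly lower in the double mutant. Of 49 listed genes, none of which another list holds, 44 were tested, so the meristem samples contain most of them. In the double mutant 42 fell and 0 rose, with a median of -1.90. In myb3r1 16 fell and 28 did not pass the test (median -0.78), in myb3r4 9 fell and 35 did not pass (median -0.64), and in the mNES line 14 rose, 0 fell and 30 did not pass (median 0.37). The mNES line was higher than myb3r4 in 36 of the 44. A broader set looked at first held 329 genes annotated as expressed in the pollen tube or sperm cells, 6 of them in the pollen list. It had 62 higher and 80 lower and a median of 0.04 in the double mutant. Its calls were 4 higher and 12 lower in myb3r1, 3 and 13 in myb3r4 and 26 and 11 in the mNES line. These calls leaned as the pollen list did. Most members did not pass the test, and the medians there were -0.02, -0.08 and -0.03. The broader set therefore did not show a shift of most members, as the listed genes did in the double mutant. The most abundant members, named after their values were seen, were AGP23 (AT3G57690) and AGP40 (AT3G20865), which encode arabinogalactan peptides, and PPME1 (AT1G69940), a pectin methylesterase of pollen. AGP23 stood at 888 TPM in Col-0, 237 TPM in the double mutant (-1.94) and 956 TPM in the mNES line. AGP40 went from 377 to 64.5 TPM (-2.61) and PPME1 from 183 to 27.0 TPM (-2.82) in the double mutant. The interaction had 4 genes positive and 1 negative, and 39 did not pass the test.

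A different share of all anther tissue was argued against for the double mutant and the mNES line, because the anther and tapetum list went the other way there, with medians of 0.65 (11 higher and 1 lower of 15) and -0.67 (0 higher and 11 lower), while in myb3r4 its median of -0.13 had the sign of the pollen list and left this open. Random differences in the buds kept at dissection stay open, since the list was written with falls of some members known; its mean differed from Col-0 by 3.23 times the largest range within a group in the double mutant (1.87 against 0.577) and by 1.13, 1.70 and 1.17 times in the mNES line, myb3r1 and myb3r4. With median-of-ratios scaling, 100% of the members called lower in the double mutant (42 of 42) and higher in the mNES line (14 of 14) kept their call. That scaling moved log2 fold changes by about -0.050 in the double mutant and 0.033 in the mNES line, in the direction of the calls. The kept calls therefore decide nothing. The small size of these shifts, beside pollen medians of -1.90 and 0.37, argued against the choice between these scalings as the whole cause. A systematic difference in bud stage at harvest may still account for the pattern, as the meiosis list moved against the pollen list in the double mutant, with a median of 0.41 (adjusted p = 0.0427, but 0.302 with an estimated correlation, 0.0677 without myb3r1myb3r4 replicate 1 and 0.0532 without myb3r1myb3r4 replicate 3), and had a median of -0.21 in the mNES line without a call (adjusted p = 0.172, but 0.0372 without GFP-MYB3R4mNES replicate 3). It cannot be told apart from an effect of the genotype on male development, which would give the same and was not tested, since the labels give no stage of the buds.

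A set of 23 genes changed at least 2-fold in the same direction in myb3r1, myb3r4 and the double mutant with an interaction of the opposite sign, a sign that the floor of the log2 scale sets for genes that fell to near 0 TPM. The 3 higher were AT5G35935, AT3G29120 and AT3G30160, and 20 were lower, MRD1 most of all. Col-0 libraries that stand apart were argued against, as the mNES line would then share the change. Its median in the direction of the mutants was -0.97, with 12 genes opposite, 10 not called and 1 alike, LHCB1.1, whose reads its near-identical neighbours share. This median covers unlike members, with examples picked after their values were seen. In the mNES line PMEI1 (AT1G48020) was at 2.21 and AT3G28810 at 2.12, while MRD1 at -0.13, HEI10 at -0.06 and AT5G35935 at 0.03 were not called. The 12 opposite genes were lower in the mutants and higher in the mNES line, as the pollen list was, and may belong to that pattern, which was not tested. The count of close pairs that follows covers all 23 genes together. Linked segments of another strain or epigenetic state in the mutant lines may contribute and stay open. Among these genes 1 pair lay within 20 kb, MRD1 and HEI10, which overlap, against a mean of 0.0975 in 10000 random sets (permutation p = 0.0922), and the pedigree of the lines is not given in the labels.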
